A study of Glycine max with 4 samples.

How the data were processed

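The samples were 2 root and 2 shoot nanoCAGE libraries of soybean (Glycine max, cultivar Williams 82), grouped by the tissue and number in their titles. The submitters used 1 µg of total RNA per library, per the labels' protocols. The files name their sequences by identifiers of a 20-sequence assembly, whose sequence and gene models were not used here. The aligner, the treatment of reads that map to several places and the software for clusters are not given in the sources used here. Soybean carries many duplicated genes, so tags of near-identical copies could have been split or joined before deposit, and single clusters are uncertain to that extent.

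The deposited count table gives raw counts of tags per start position, strand and library, per the file headers. As read here it held 479104 positions, 67.3% of the 711688 positions in the TPM table. It covered sequences 1 to 12 and, of sequence 13, the plus strand and the minus strand up to position 31697699, where it ended in 1 broken line that was left out. The deposited TPM table gives 1 value per tissue and position on all 20 sequences, per the file headers. On positions in both tables each TPM value was a power function of the summed counts of the 2 replicates, with an exponent of 1.00 in root and 0.994 in shoot, and 1 tag was worth 0.286 and 0.329 TPM. Inverted, 100% of the TPM values came out as whole tags within 0.001. The count table held 69.8% of the pooled root tags and 68.0% of the pooled shoot tags. Totals per library in the text are those of the count table and not the full depth.

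The deposited lists of tag clusters give start, end and a TPM score per cluster for the pooled replicates of each tissue, and the number of start positions as another column, per the file headers. All 19249 root and 17081 shoot clusters were rebuilt exactly from the TPM table by joining positions of 1 TPM or more in either tissue over gaps of up to 150 bp. The rebuilt set had 1861 more clusters in root and 3254 more in shoot, all of a single position and below 1 TPM in that tissue. A weak start is thus listed in 1 tissue partly by this threshold. Coordinates are those of the deposited files, counted from 1. The only gene table at hand belonged to another assembly (Glycine_max_v4.0), and none of its coordinates were used. For this reason the comparisons of genes, gene lists and gene-level promoter use, and those of initiator bases, TATA motifs and location on genes, which were part of the design, are not analysed here.

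Root and shoot clusters on the same strand within 100 bp were merged into 23330 regions, of which 15741 lay in the part covered by counts. They held 86.8% to 88.2% of the tags of each library. The 10 strongest clusters held 10.9% to 12.4% of a library's tags in clusters. The main test was edgeR's quasi-likelihood test with TMM scaling (the trimmed mean of M values) and the filterByExpr filter, which left 7183 clusters, with tissue as the only term and Benjamini-Hochberg adjustment at 0.05. Scaled CPM are counts brought to a common library total after TMM factors of 1.13 and 1.16 in root and 0.899 and 0.852 in shoot. Named clusters were the 8 per direction with the largest fold fitted by edgeR among called clusters with a mean of 50 CPM or more in the higher tissue and no overlap between the libraries of the tissues. This rule and the tests were fixed before the data were examined, except where the text says otherwise. Where a tissue had 0 tags, the fold was computed against a floor of 3 counts over its 2 libraries. Counting intervals of ratios were exact binomial intervals at 95%, and those of shares were Wilson intervals.

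Counts were simulated for the 7183 clusters with 200 changed, and 6545 of them passed the count filter again. Among changed clusters that passed it, the test recovered 2.38% of changes of 1.5-fold, 18.4% of 2-fold, 80.0% of 4-fold and 97.7% of 8-fold, with 7 false calls. Changed clusters that the filter removed are left out of these rates, so recovery over all 200 could be lower. The simulation used 1 spread for all clusters (dispersion 0.05) and changed a far smaller share of clusters than the test called in the data. These rates therefore need not hold for the data, and clusters not called may still differ by 2-fold. Use of neighbouring clusters was tested with edgeR's diffSpliceDGE (Simes test per group) in groups of clusters separated by gaps of up to 500 bp, each cluster holding 10% or more of the group's tags in 1 tissue. This replaced the comparison by gene. In 148 simulated groups with 50 changed by 8-fold it recovered 60.0% with 0 false calls.

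The most used position was compared between library pairs in clusters with at least 10 tags in each library, after thinning all libraries to 655935 tags. Widths were recomputed in clusters with at least 50 tags in each library, thinned to 50. The alternatives tried were RLE size factors, DESeq2, no count filter, a replicate block, thinning, a test against a fold of 2, leaving out each library, merging overlapping clusters only, other tag minimums, shifts and width limits, and, chosen after the data were examined, scaling to total tags and settings of the neighbouring-cluster test. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.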

Results

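Transcription start sites were mapped by nanoCAGE in roots and shoots of Williams 82, the soybean cultivar whose genome serves as the reference of the species. NanoCAGE sequences the 5′ ends of capped RNA, so that each tag is taken here to mark the base at which a transcript starts. The number of tags measures how much RNA with that 5′ end was present, and use of a start refers here to this amount. The plants were 2 weeks old and had grown under white light of 300 µmol per square metre per second with 12 h of light per day, and each library was made from 1 µg of total RNA. Roots and shoots had 2 libraries each, which the labels number 1 and 2 without saying that they came from separate plants. P-values of tests between libraries therefore measure only the spread between these samples, which may be technical, and p-values of tests over clusters or pairs of clusters take these as units and measure no spread between libraries.

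The table of counts per library held 1000476 tags for root replicate 1, 874004 for root replicate 2, 901261 for shoot replicate 1 and 655935 for shoot replicate 2, on sequences 1 to 12 and part of sequence 13 of a 20-sequence assembly. A pooled table gave 1 value per tissue for all 20 sequences in TPM, here a power function of the tag number with an exponent close to 1 and not a share of a common total: the values summed to 771467 in root and 735581 in shoot, from 2685956 root tags and 2291657 shoot tags. Starts that lie close together on 1 strand form a tag cluster, the usual unit of a promoter in this kind of data, and clusters are named here by sequence, strand, start and end. Gene names are not attached to the positions, because no annotation of the assembly that the sequence names of the files belong to was used here. Across clusters, log2 tag levels correlated at r = 0.911 between the root libraries and 0.921 between the shoot libraries, against 0.259 to 0.370 for the 4 root-shoot pairs. Clusters are not independent replicates, and these values describe the libraries. The 2 libraries of a tissue did not hold the same counts (chi-square per degree of freedom 6.84 in root and 3.52 in shoot), a value that amplification alone can raise above 1 and that does not show separate plants. Each library was counted as a sample because the labels list it as one.

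The first question was which start regions the 2 tissues use at all. Most tags in such regions came from those listed in both tissues. Of 23330 merged regions on the 20 sequences, 12961 (55.6%) had a tag cluster in both lists, and they held 96.5% of the root TPM and 93.2% of the shoot TPM that lay inside merged regions. Of all TPM, with starts outside the regions included, these shares were 83.7% and 81.3%. The 6275 regions listed in root alone held 3.31% of the root TPM inside merged regions (2.87% of all root TPM), with a median of 1.72 TPM. The 4094 regions listed in shoot alone held 6.46% of the shoot TPM inside merged regions (5.64% of all shoot TPM), with a median of 1.95 TPM. Being in 1 list was not the same as being silent in the other tissue: 2919 of the regions listed in root alone and 2166 of those listed in shoot alone had no tag in the other tissue.

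The authors' root list held 19249 tag clusters and the shoot list 17081. Root clusters had a median width of 7 bp and shoot clusters of 11 bp. Clusters of 10 bp or less made up 54.5% of the root list (95% Wilson interval 53.8 to 55.2) and 49.3% of the shoot list (48.5 to 50.02), and clusters of a single position made up 35.4% and 29.4%. Root clusters overlapped a shoot cluster in 67.3% of cases (66.7 to 68.0) and shoot clusters a root cluster in 75.9% (75.3 to 76.6). Among clusters of 5 TPM or more, which numbered 9237 in root and 8532 in shoot, 28.7% and 24.8% were 10 bp or less, and 90.9% and 88.4% overlapped the other list. Each list came from pooled replicates, so these differences have no replicate check. All binomial intervals and count floors in the text cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

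The main comparison asked which clusters were used more in root or in shoot. Root and shoot differed at 52.9% of the clusters with enough tags to test. Of 7183 clusters, 2119 were higher in shoot and 1684 were higher in root. Clusters higher in shoot carried 57.8% of the shoot tags in tested clusters and 10.1% of the root tags, and clusters higher in root carried 41.1% of the root tags and 7.67% of the shoot tags. The median log2 difference was 3.18 in clusters higher in shoot and 2.44 in clusters higher in root, and 1119 clusters were over 8-fold higher in shoot against 669 in root. With the clusters at 0 tags in the other tissue set to the bound that 3 counts allow, the medians were 3.18 and 2.42 and the numbers over 8-fold 1119 and 636. With no count filter, 15741 clusters were tested, and 1803 were over 8-fold higher in shoot against 1262 in root.

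The calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 4198 clusters had an unadjusted p below that level. The split by direction depended on the scaling. Scaled to total tags, chosen as an alternative after the data were examined, 43.4% of 4107 called clusters were higher in shoot, against 55.7% of 3803 with the trimmed mean of M values, and the median log2 difference of all tested clusters moved from 0.06 to -0.32. The order of the medians without shoot replicate 1 depended on which clusters were taken. Among clusters called without it, the median log2 difference was 3.79 in root and 3.66 in shoot. For the clusters called with all libraries, the same fit gave medians of -2.91 for those higher in root and 2.94 for those higher in shoot. Scaled to total tags, the medians of these same clusters were -2.81 and 2.80.

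**Figure D1:**
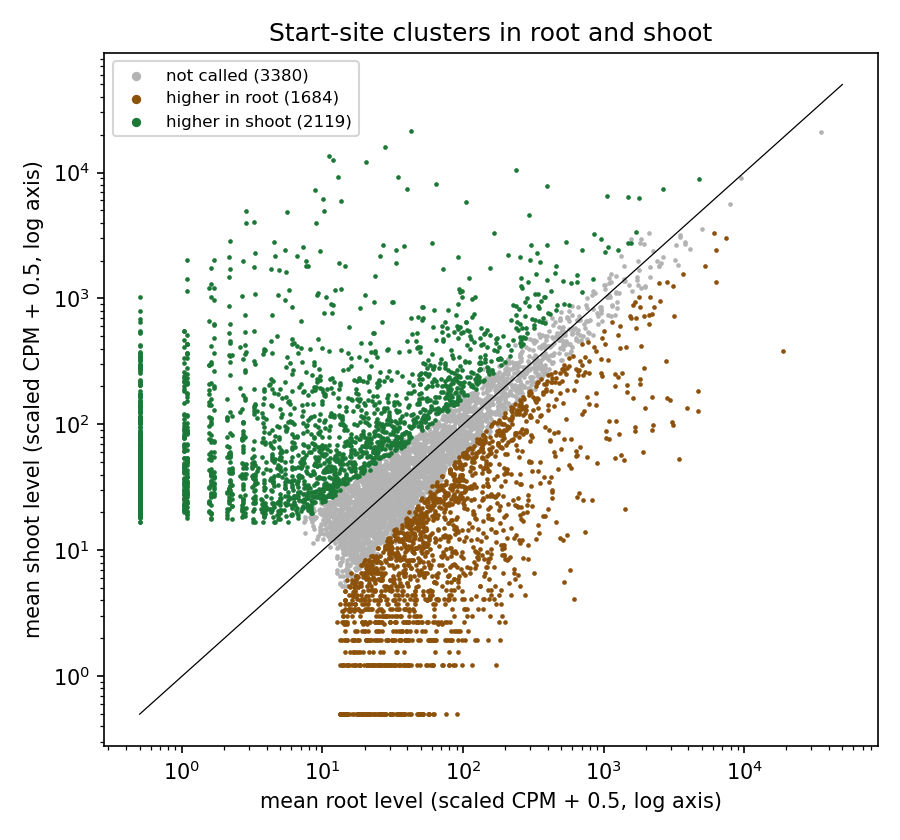
Mean root level (horizontal) against mean shoot level (vertical) of the 7183 tested clusters, in scaled CPM plus 0.5 on log axes, with 1 point per cluster and n = 2 libraries per tissue. The 2119 clusters higher in shoot lie above the line of equal level, the 1684 clusters higher in root below it, and the columns and rows of points at the left and bottom hold clusters with few or no tags in 1 tissue.

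The strongest starts among those called higher in shoot had few tags in root. The 5 most abundant clusters among those higher in shoot, chosen after their values were seen, lay at 12225 to 21380 CPM (counts scaled to a common library total) in shoot and at 10.7 to 42.4 CPM in root. The first, on sequence 5 plus strand at 34430489 to 34431349, had 21380 ± 3109 CPM in shoot (SD, n = 2) and 42.4 ± 12.9 CPM in root, a ratio of 504. Sequence 5 also held the next, on the minus strand at 2014172 to 2015032, with 16041 ± 2976 CPM in shoot against 27.2 ± 3.2 CPM in root. On sequence 8 plus strand at 44710095 to 44710243 the levels were 13648 ± 3158 and 10.7 ± 1.7 CPM, a ratio of 1279. On sequence 1 plus strand at 47966432 to 47966806 they were 12528 ± 2998 and 11.3 ± 4.1 CPM, and on sequence 7 minus strand at 11558427 to 11558595 they were 12225 ± 1971 and 20.02 ± 1.4 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 difference at the sequence 5 plus-strand cluster was 8.97 ± 0.51 (SE), with the highest adjusted p of the 5, 4.74e-07.

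Clusters with no root tag at all reached 1023 CPM in shoot. In all, 336 of the clusters higher in shoot had 0 tags in both root libraries. Without root replicate 1, 463 of the same clusters were at 0 tags, at up to 1210 CPM in shoot, and without root replicate 2, 454 were, at up to 4991 CPM. The 8 clusters with the largest fold fitted by edgeR were taken by a fixed rule: a mean of 50 CPM or more in the higher tissue, and both of its libraries above both of the other. The first of them, on sequence 8 plus strand at 10709122 to 10709128, held 980 and 295 tags in the shoot libraries (1023 ± 574 CPM, SD, n = 2) and 0 in root, at least 611-fold higher in shoot against a floor of 3 counts over the 2 root libraries. The same bound was at least 474-fold on sequence 10 plus strand at 45327523 to 45327951, at least 410-fold on sequence 3 minus strand at 46252225 to 46252319, and at least 387-fold on sequence 1 plus strand at 51794694 to 51794735. It was at least 332-fold on sequence 8 plus strand at 16238821 to 16238828, at least 321-fold on sequence 6 plus strand at 1189114 to 1189243, and at least 320-fold on sequence 6 minus strand at 14738990 to 14739105. The eighth cluster, on sequence 7 minus strand at 5298581 to 5298689, had 1 root tag, in replicate 2, against 2037 ± 365 CPM in shoot, a ratio of 3431 with a 95% counting interval of 670 to 147562. Its log2 difference of 11.45 was 10.52 without root replicate 1 and 13.48 without root replicate 2. With 1 shoot library left out, the bound moved by over 1.5 times at the first cluster (369-fold without shoot replicate 1) and at the sequence 10 cluster (294-fold without shoot replicate 2). At the clusters with no root tag, the floor bounds leave out counting error in shoot. Lower limits of their exact 95% counting intervals were smaller, from 255-fold on sequence 6 minus strand to 531-fold at the first cluster. Most of this drop lay on the root side, because at 0 root tags these two-sided intervals allow more than the 3 counts of the floor. The measured ratio of 1279 on sequence 8 plus strand at 44710095 was above all these bounds. The highest adjusted p of the 8 was 3.32e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

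The starts called higher in root were led by 1 cluster. The most abundant cluster higher in root, on sequence 9 plus strand at 12733167 to 12733906, had 18806 ± 2275 CPM in root (SD, n = 2) and 386 ± 442 CPM in shoot, a log2 difference of -5.59 ± 0.86 (SE) with an adjusted p of 0.000313 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The shoot libraries were far apart there, at 698 CPM in replicate 1 and 73.2 CPM in replicate 2, and the log2 difference was -8.02 without shoot replicate 1 and -4.70 without shoot replicate 2. The 10 most abundant clusters over 8-fold higher in root, the sequence 9 cluster included, lay at 2797 CPM or more in root. These were also picked after their values were seen. Their shoot levels were 2.41% to 13.4% of the root level in replicate 1 and 0.22% to 9.34% in replicate 2. The next 4 by abundance among all clusters called higher in root, again chosen after their values were seen, changed by much less. On sequence 6 minus strand at 2425404 to 2425501 root had 6280 ± 2333 CPM and shoot 1354 ± 301 CPM, a ratio of 4.64. The ratios were 2.63 on sequence 4 minus strand at 49003680 to 49003764, 2.44 on sequence 5 minus strand at 3640975 to 3641055 and 1.86 on sequence 6 plus strand at 3664281 to 3664320. These last 3 no longer passed when tested against a fold of 2, and the sequence 5 and sequence 6 plus-strand clusters did not pass without shoot replicate 1 (adjusted p 0.0637 and 0.0768 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), nor the latter without shoot replicate 2 (0.107). Over all alternatives, by edgeR or DESeq2 with Benjamini-Hochberg adjustment, the adjusted p ran from 2.42e-07 to 0.103 for the sequence 4 cluster, from 1.48e-06 to 0.183 for the sequence 5 cluster and from 0.00186 to 0.633 for the sequence 6 plus-strand cluster.

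Few clusters higher in root were without a tag in shoot, and their number and level rest on shoot replicate 1. Of the clusters higher in root, 96 had 0 tags in both shoot libraries, at 89.96 CPM or less in root. Without shoot replicate 1, 412 of the same clusters were at 0 tags, at up to 611 CPM in root, and without shoot replicate 2, 123 were, at up to 92.1 CPM. The rule, which ranks by the fold that edgeR fitted, took 8 clusters that were all at 0 in shoot and between 51.2 and 89.96 CPM in root. The measured ratio of the sequence 9 cluster named above, 48.8, was higher than each bound given next for these 8. On sequence 10 minus strand at 45652264 to 45652271 root had 89.96 ± 75.2 CPM (SD, n = 2), at least 34.9-fold higher than shoot against a floor of 3 counts over the 2 shoot libraries. On sequence 11 plus strand at 10156749 to 10156755 root had 75.5 ± 4.1 CPM, at least 29.3-fold higher. The bounds were at least 24.1-fold on sequence 6 minus strand at 989649 to 989654 and at least 23.7-fold on sequence 12 plus strand at 3877276 to 3877283. They were at least 22.1-fold both on sequence 7 minus strand at 16748651 to 16748675 and on sequence 2 minus strand at 7770625 to 7770694. The last 2 were at least 21.7-fold on sequence 12 minus strand at 37398014 to 37398049 and at least 19.9-fold on sequence 11 plus strand at 16908920 to 16908930. Without root replicate 1 the bound was 14.3-fold on sequence 10, 11.1-fold on sequence 7 and 11.98-fold at the last cluster on sequence 11. Without root replicate 2 it was 55.5-fold on sequence 10 and 14.3-fold on sequence 2, and the other bounds moved by 1.5 times or less when either root library was left out. The highest adjusted p of the 8 was 0.000611 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

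Across clusters over 8-fold higher in root, the shoot libraries differed from each other. Shoot replicate 1 held more scaled tags than shoot replicate 2 in 237 of 268 such clusters with at least 5 shoot tags (88.4%), with a median log2 ratio of 1.35. The median of the same ratio was 0.02 in clusters not called and -0.10 in clusters over 8-fold higher in shoot. Without shoot replicate 1, the median log2 difference of the clusters called higher in root with all libraries was -2.91, against -2.44 with it. Part of this shift was common to both directions. The median of the clusters called higher in shoot moved from 3.18 to 2.94, and that of all tested clusters from 0.06 to -0.15.

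**Figure D2:**
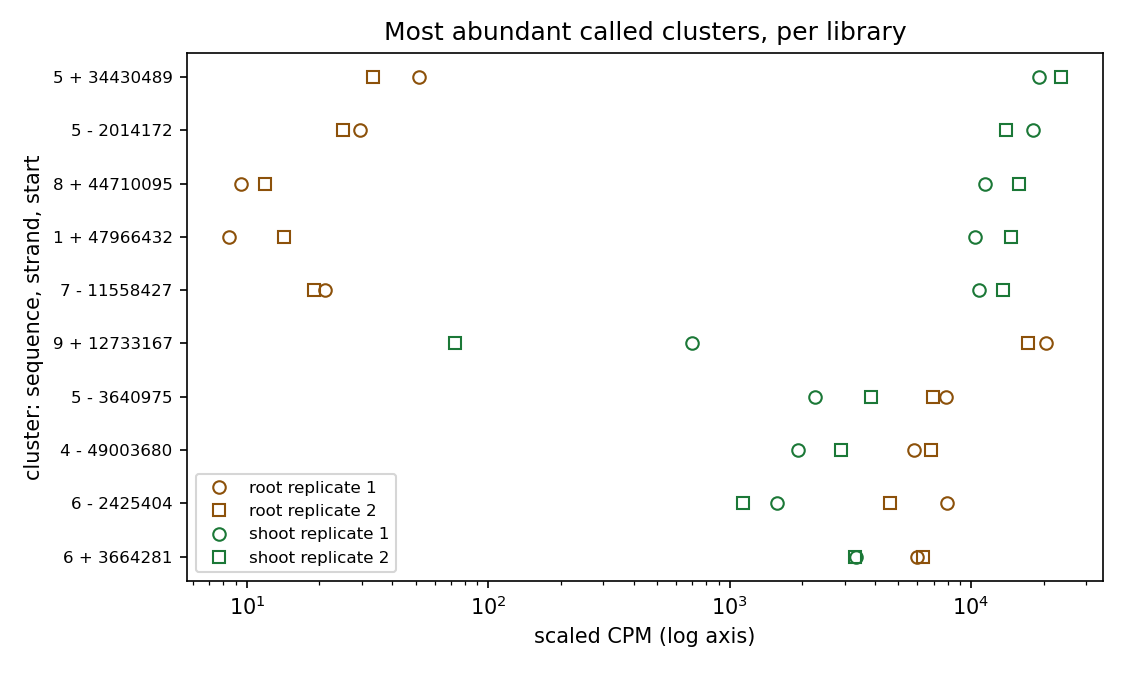
Scaled CPM on a log axis in each of the 4 libraries for the 5 most abundant called clusters per direction, named by sequence, strand and start; circles are replicate 1 and squares replicate 2, brown for root and green for shoot. The upper 5 lie at 42.4 CPM or less on average in root, and the sixth from the top, on sequence 9, has shoot values of 698 and 73.2 CPM.

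Several of the strongest starts of both tissues did not pass the test. The most abundant of all, on sequence 4 plus strand at 49678019 to 49678129, had 35198 ± 5359 CPM in root and 20827 ± 4234 CPM in shoot (SD, n = 2), with an adjusted p of 0.130 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On sequence 7 minus strand at 15415571 to 15415690 the levels were 9482 ± 631 and 8989 ± 21.5 CPM, and on sequence 13 plus strand at 32885544 to 32885705 they were 7883 ± 1678 and 5595 ± 563 CPM. These clusters were chosen after their values were seen.

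Sequences outside the count table gave shares close to those of the covered part in the pooled TPM, without replicates and so without a test. Among regions of 5 TPM or more in either tissue, 16.1% were at least 5-fold higher in shoot and 17.2% at least 5-fold higher in root (4059 regions), against 16.4% and 17.5% of the 8447 regions that the count table covered. In this scaling root led slightly in both parts, while in the tested counts more clusters were over 8-fold higher in shoot (1119 against 669), with another scaling and another limit. With the tested counts scaled to total tags, 1014 clusters were over 8-fold higher in shoot against 776 in root. The strongest shoot-leading region there lay on sequence 14 minus strand at 632067 to 632095, with 4493 TPM in shoot and 15.8 in root. On sequence 18 plus strand at 2149963 to 2150155 shoot had 3417 TPM and root 13.5. Root led on sequence 17 plus strand at 11386948 to 11387081, with 5584 TPM against 90.1, and on sequence 16 plus strand at 3566171 to 3566485, with 7243 against 1104. On sequence 19 minus strand at 40020086 to 40020393 the values were 4650 TPM in root and 4584 in shoot.

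A map of starts can also show whether neighbouring clusters on 1 strand are used in other proportions in the 2 tissues. This was so in 15 of 148 groups of clusters with gaps of up to 500 bp, a comparison set up after the data were examined. In 10 of these 15, the most used cluster of the group was a different one in root and in shoot, in both libraries of each. On sequence 12 plus strand the upstream cluster at 3716142 to 3716181 held 48.3% ± 15.7 of the group's root tags (SD, n = 2) and 0.19% ± 0.27 of its shoot tags, the rest lying at 3716428 to 3716538. The root libraries had 16 and 22 tags in the upstream cluster and 27 and 15 in the other. Counting error is large in shares of so few tags. On sequence 1 minus strand the downstream cluster at 2822754 to 2822838 held 4.81% ± 2.04 in root and 73.5% ± 7.7 in shoot.

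On sequence 6 plus strand a single downstream position, 10988420, held 61.2% ± 1.7 of the group's root tags (SD, n = 2) and 3.23% ± 0.15 of its shoot tags. The downstream cluster on sequence 8 plus strand at 2927196 to 2927200 held 56.5% ± 6.0 in root and 1.63% ± 2.31 in shoot. The root libraries had 23 and 17 tags there, and 21 and 11 in the upstream cluster. The upstream cluster on sequence 6 minus strand at 3588541 to 3588547 held 5.05% ± 2.20 in root and 64.0% ± 12.3 in shoot, and the upstream cluster on sequence 10 plus strand at 24543775 to 24543827 held 21.3% ± 0.8 and 2.01% ± 0.09. On sequence 6 minus strand the shoot libraries had 21 and 16 tags upstream and 17 and 6 downstream. These 6 groups had the smallest adjusted p, at most 0.000458 by edgeR's test of differential use with Benjamini-Hochberg adjustment over the 148 groups. Without shoot replicate 1, 7 groups passed, and without shoot replicate 2, 10 did.

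**Figure D3:**
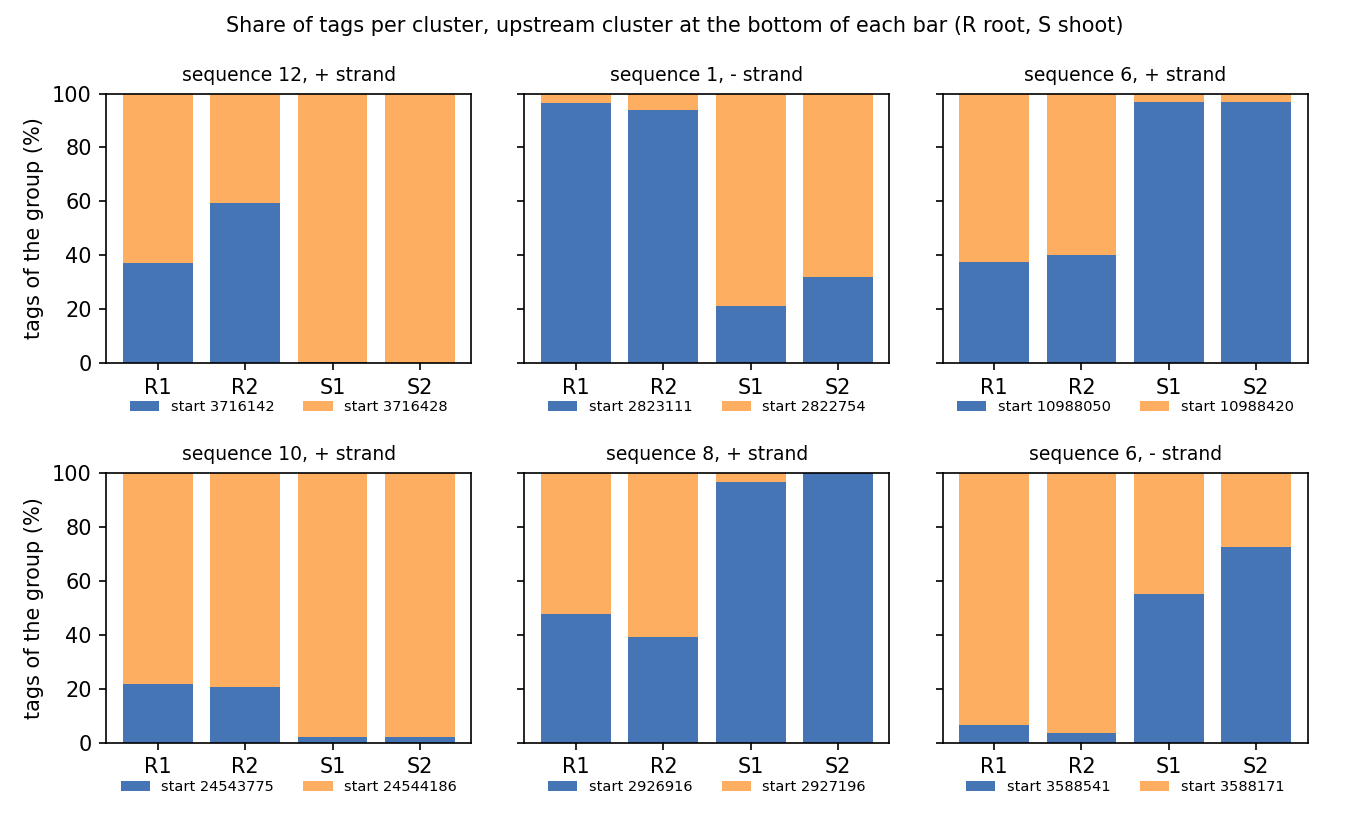
Share of tags (percent) that each of 2 neighbouring clusters holds of its group, per library (R1 and R2 root, S1 and S2 shoot), for the 6 groups with the smallest adjusted p; the upstream cluster is at the bottom of each bar. Both root bars differ from both shoot bars in each group, for example 37.2% and 59.5% against 0.39% and 0% for the upstream cluster on sequence 12.

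Within clusters, the most used position was mostly shared by the tissues. With all libraries thinned to the smallest, it lay 10 bp or more apart in 17.1% ± 0.31 of 3162 clusters for the 4 root-shoot library pairs (SD over the 4 pairs, range 16.6 to 17.3), and in 12.9% and 13.3% for the pairs within root and within shoot. All 4 values between tissues were above both values within tissues, and 2 against 2 libraries cannot give a two-sided p below 0.333. In 106 clusters both libraries of each tissue shared their most used position and the tissues lay 10 bp or more apart, against 17 and 27 for the other 2 ways of pairing the 4 libraries. With all tags counted, 79 of the 106 still met this, and 118 clusters did in all, against 15 and 25 for the other pairings. The cluster on sequence 5 plus strand at 6440747 to 6440911, chosen after its values were seen, met it only when thinned: with all tags, root replicate 2 had 22.0% at the root position and 25.6% at the shoot position. The shoot position was downstream of the root position in 44 of the 106 (two-sided exact binomial p = 0.0982), a split that did not pass 0.05.

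The example with the most tags, chosen after its values were seen, lay on sequence 3 plus strand at 1491276 to 1491371. Position 1491283 held 29.1% and 39.0% of the root tags and 5.72% and 5.62% of the shoot tags, while position 1491321, 38 bp downstream, held 8.99% and 3.90% in root and 14.8% and 15.2% in shoot. This cluster was also higher in shoot, with a log2 difference of 5.46 and an adjusted p of 2.8e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A cluster on sequence 13 minus strand at 25009845 to 25009920 did not pass that test (log2 difference 0.38) and still moved its main position by 30 bp. There position 25009880 held 31.3% and 30.6% of the root tags against 16.9% and 19.3% of the shoot tags, and position 25009850 held 20.6% and 17.4% against 35.0% and 37.3%. On sequence 2 plus strand at 2075820 to 2075903 the main position was 2075901 in root (36.9% and 38.4%, against 25.8% and 26.9% in shoot) and 2075856 in shoot (37.1% and 33.8%, against 25.9% and 23.3% in root).

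**Figure D4:**
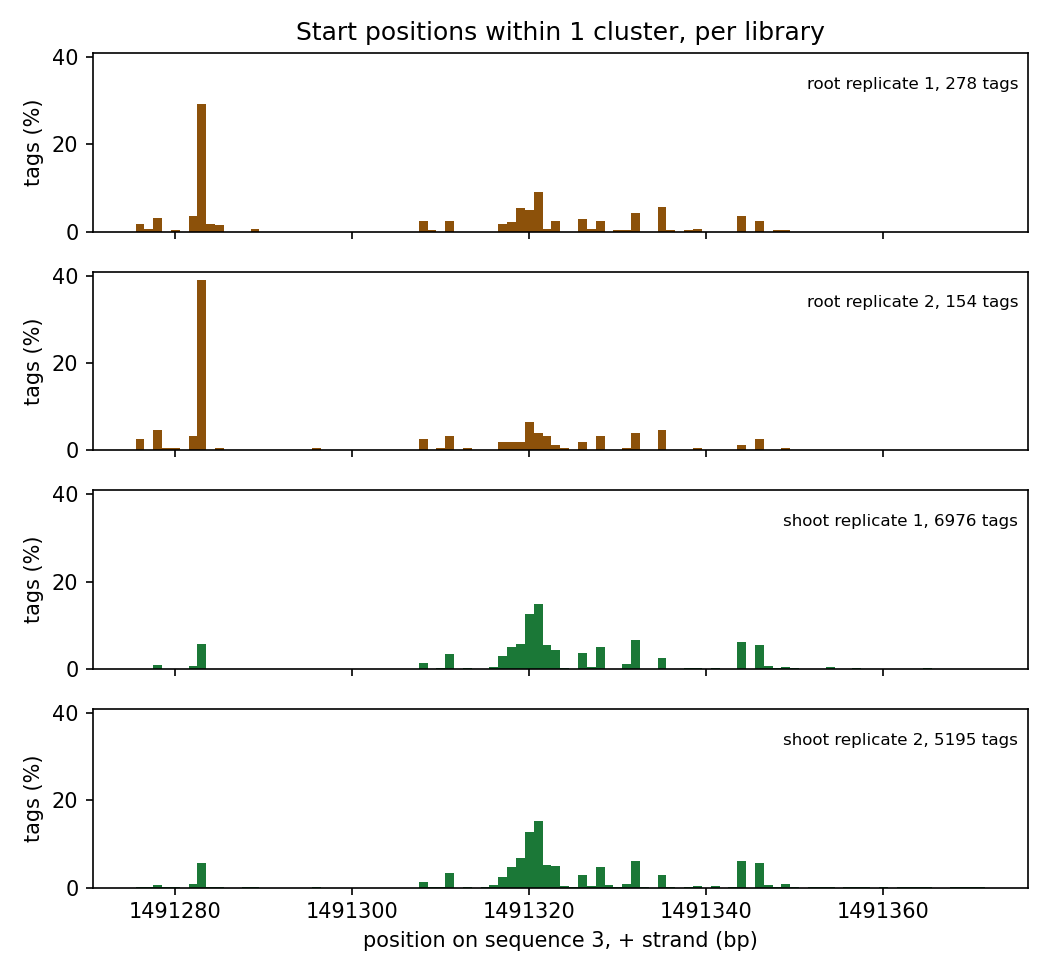
Percent of each library's tags at each position (bp) of the cluster on sequence 3 plus strand, with root replicates in brown and shoot replicates in green, and the number of tags given in each panel. Position 1491283 is the highest bar in both root panels (29.1% and 39.0%), and position 1491321 is the highest in both shoot panels (14.8% and 15.2%).

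In clusters with at least 50 tags in every library, widths at equal tag number were close in the 2 tissues. The interquantile width, the span from the 10% to the 90% point of a cluster's tags, was recomputed at 50 tags per library in 1114 clusters. The median was 27.5 ± 0.71 bp in root and 27.5 ± 0.71 bp in shoot (SD, n = 2). Clusters of 10 bp or less made up 33.2% in both root libraries and 32.5% and 33.0% in the shoot libraries. Mean widths were 45.4 ± 0.29 bp in root and 46.6 ± 0.17 bp in shoot, so both shoot libraries lay above both root libraries by this measure. The smallest two-sided p of 2 against 2 libraries is 0.333 in an exact permutation test. Clusters with few tags in 1 tissue take no part in this comparison. At 50 pooled tags in the higher tissue, the median width was 12 bp in clusters higher in root and 30 bp in clusters higher in shoot.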

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

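The count of clusters without a tag in shoot replicate 1 was chosen as a test after the result was seen. Tags outside all merged clusters take no part in the comparisons. They made up 12.6% of the tags in root replicate 1, 13.2% in root replicate 2, 12.5% in shoot replicate 1 and 11.8% in shoot replicate 2.

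Clusters far higher in root held more tags in shoot replicate 1 than in shoot replicate 2. A difference in depth is argued against by the median log2 ratio of scaled tags, 1.35 (95% bootstrap interval 1.14 to 1.62) against 0.02 in clusters not called. A candidate explanation is a small admixture of root tags at a fixed share of the root level. The excess came to 4.46% of the root level over all 669 clusters. Of the 204 clusters with 3 or more expected tags, 0 had no tag in shoot replicate 1, against 1.67 expected by Poisson counting. In shoot replicate 2, 43 had no tag. The 4.46% was taken from these same clusters and libraries, and the expected tags left out the shoot's own use of these starts. The count therefore cannot tell admixture from other sources of tags. Of the 37 clusters with 20 or more expected tags, 0% held under 25% of them (upper 95% limit 9.49%), which are too few to decide, and the excess was far from even among them, from -3.55% to 18.5% of the root level (quartiles 2.76% and 5.86%), so a single fixed share is not established. The labels name no biological difference between the shoot libraries and none was tested, so a difference in the plants or plant parts harvested stays open.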

How the results depend on the processing

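Scaling to total tags and all settings of the neighbouring-cluster comparison were chosen after the data were examined. The 3803 called clusters became 2694 to 5363 under the alternatives, all within 1.5 times, and none of the calls that an alternative kept was reversed. Similar totals did not mean the same clusters. Of the 3803, the alternatives on all libraries kept 2694 (test against a fold of 2) to 3803 (merging overlapping clusters only), and DESeq2 kept 2946. Fits with 1 library left out lost calls and gained others. Tested against a fold of 2, 1086 clusters were higher in root in place of 1684, a stricter question by construction. Of 312 values for 26 named clusters under 12 alternatives, 306 kept direction and side of the threshold and 6, in 3 abundant root clusters, kept the direction only. Leaving out 1 library gave 3124 to 3909 calls, 1453 to 1666 of them higher in root and 1665 to 2243 in shoot, with the lone library assumed to vary like the other tissue. With the replicate block 3467 clusters were called. Deviations of root replicate 1 and shoot replicate 1 from their tissue means correlated at r = -0.05 across clusters. With 2 libraries per tissue, this value cannot show whether same-numbered libraries share plants, harvest or batch.

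Neighbouring-cluster groups passed in 16 to 20 cases under the other settings in place of 15, with 20 under the replicate block, and in 7 to 22 with 1 library left out. The most used position differed between tissues in 10.1% of clusters with at least 50 counts in each library (6.89% within tissues) and in 27.8% at any difference of 1 bp or more (22.9% within), and in 16.9% to 17.2% with 1 library left out. With narrow set at 5 bp, the shoot minus root difference in the recomputed width share was 0.54 percentage points in place of -0.45, and the list shares were 46.6% in root and 41.0% in shoot. That difference was -0.72 to -0.18 with 1 library left out. At 5 TPM or more the lists fell to 9237 and 8532 clusters, with narrow shares of 28.7% and 24.8% and overlaps of 90.9% and 88.4%, by removal of weak clusters. Reciprocal overlap of 50% was met by 58.1% of root and 65.5% of shoot clusters. The cause of the other shifts was not tested. Alternatives for genes, gene lists, promoter use by gene, initiator bases, TATA motifs and location on genes were not run. At 0 tags depth limits a fold through the floor of 3 counts, which is 2.58 CPM in shoot and 1.67 CPM in root.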

Other observations

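The comparisons of width by direction, of correlations by distance on 1 strand, of place on the sequences and of dense windows were chosen as tests after the result was seen. Clusters that were higher in root had sharper starts. At 50 tags in the higher tissue, 47.8% of 1309 clusters higher in root were 10 bp or less wide, with a median of 12 bp, against 31.3% of 1474 clusters higher in shoot, with a median of 30 bp, and 27.7% of 2037 clusters not called. The odds ratio of root against shoot, stratified by level, was 2.11 (95% interval 1.79 to 2.49). Among clusters over 8-fold higher, 57.0% in root and 31.7% in shoot were 10 bp or less.

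Starts lay mostly toward the ends of the sequences. Of 23330 merged clusters, 19.6% lay in the central 50% of the stretch from base 1 to the last position with a tag, and full 5 Mb windows held a median of 53 clusters with a range of 1 to 343. Tested clusters were called in 54.2% of cases in the central part and in 52.6% outside it (two-sided Fisher's exact test p = 0.295). Some 10 kb windows were full of starts: on sequence 11 plus strand, 708 positions from 7480631 to 7489551 held 1764 TPM in shoot and 2.00 TPM in root, and on sequence 10 minus strand, 915 positions from 54982652 to 54988346 held 182 TPM in shoot and 1275 TPM in root, against a median of 4 positions per window with a tag.

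Narrow clusters were called more often than wide ones, 65.8% of 1652 against 53.5% of 3168 (odds ratio 1.67, two-sided Fisher's exact test p = 2.13e-16; clusters are not replicates). A difference in tag number is argued against as the whole cause, since the odds ratio stratified by mean level was 1.60 (95% interval 1.41 to 1.81). The excess lay mostly on the root side: stratified in the same way, the odds ratio was 2.31 (1.99 to 2.69) for clusters higher in root against those not called and 1.16 (1.00 to 1.35) for clusters higher in shoot. A technical origin of the sharp starts was not tested.

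Neighbouring clusters changed together on the same strand. Without gene models, pairs of clusters of 1 gene could not be told apart from pairs of different genes. Among 10 kinds of pairs, log2 differences correlated across pairs at r = 0.89 for same-strand pairs within 1 kb, 0.85 at 1 to 3 kb, 0.31 at 5 to 10 kb and 0.02 at 10 to 50 kb, and at 0.47 (95% bootstrap interval 0.13 to 0.68) for 32 divergent pairs within 1 kb, of which 50% changed in the same direction. Pairs are not independent replicates. The two-sided permutation p was 0.0001, the smallest that 10000 permutations can give, for the first 3 kinds (0.0002 after Benjamini-Hochberg adjustment), 0.18 for the fourth (0.20 adjusted) and 0.0062 for the divergent pairs (0.00886 adjusted). Whether any pair of clusters within 10 kb changes together could not be decided: r was -0.099 (-0.234 to 0.0432) for convergent pairs at 1 to 10 kb, but 0.25 (0.146 to 0.352) for divergent and 0.54 (0.475 to 0.592) for same-strand pairs at that distance, and 0.90 for 11 convergent pairs within 1 kb, so closeness itself stays open for the divergent pairs.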
